A study of Mus musculus with 6 samples.

How the data were processed

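The data are gene counts from RNA sequencing of sorted mouse bone marrow progenitors, with 3 animals in each of 2 groups. Per the labels' protocols, marrow was flushed from femurs, lineage-positive cells were removed with magnetic beads, progenitors were sorted by flow cytometry, and libraries were made with the Clontech SMARTer Ultra Low Input RNA kit. This kit primes on poly(A) tails and amplifies full-length cDNA. The protocols do not describe the libraries as stranded, so reads of overlapping and antisense genes cannot be told apart, and no molecular identifiers are described, so precision from read counts covers counting error only.

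The deposited table holds whole-number counts of reads per gene, without normalization, for all 6 samples. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a to GRCm38.p6. The counting tool, its settings and the annotation release are not given in the sources used here. The table has 35434 Ensembl gene identifiers, of which 35202 (99.35%) matched GENCODE M21 on GRCm38 and 232 did not. It covers 21831 of the 21951 protein-coding genes of that annotation and many pseudogenes, but 4 of its 5854 lincRNA genes, so long noncoding RNA was not analysed here. Where several identifiers share a symbol (78 identifiers), the one with most counts carried it. Symbols, positions and overlaps of exons come from GENCODE M21. Total counts per library ran from 25411341 to 36423876. Pairs of libraries of the same group differed by a chi-square of 10.8 to 58.5 per gene, above counting noise alone, so no pair was counted as 1 library. This does not tell separate animals from repeat libraries of 1 RNA, and the labels give 3 animals per group.

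Groups were taken from the sample titles. Genes were kept with the default filter of edgeR (filterByExpr, minimum count 10, minimum total 15), which left 13209 genes. Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are Inflammation minus Control, and their standard errors come from the fitted value and its F statistic. CPM values are TMM-scaled and given as mean ± SD over 3 animals. The common biological coefficient of variation was 16.3%.

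Before the data were examined, 38 gene lists were fixed from textbook knowledge of progenitors, inflammation, metabolism, other marrow cell types and technical checks. Those with at least 5 tested members, 37 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes and adjusted over lists. Each list was also tested with an estimated correlation and with fry, and the number of its members past the gene test is given over all genes and adjusted over the list alone. The genes named in the text were also fixed by rule. They are the 10 with the largest log2 fold change in each direction among genes past the threshold with a mean log2 CPM of at least 3 and no overlap of the groups, leaving out unnamed and pseudogene models; up to 4 members with the smallest p of each list that passed or held 3 or more passing genes, at a mean log2 CPM of at least 1; a fixed panel of progenitor, granule, lipid and contamination markers; and the genes of the sort. Members of lists outside this rule are named only where they make up a count of 5 or fewer.

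The gene test was tried on simulated counts with the means and library sizes of these 6 samples, with 13209 genes in the fit. For this comparison it recovered 19.4% of 67 genes changed 1.5-fold, 62.7% of 67 changed 2-fold and 84.8% of 66 changed 4-fold, and 11 of 122 calls (9.02%) were false. The list test recovered the list that was moved and called 1 other, and 20 data sets without any change gave 1 list call and 7 gene calls in all. Simulated genes vary independently, so these figures do not show how real correlation between genes affects the list test. Simulated libraries also shared 1 dispersion per gene. The real libraries were less even, with limma sample weights from 0.263 (Inflammation 2) to 2.89 (Control 3). The figures for the gene test may therefore not carry over to these data.

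Alternatives set before the data were examined were RLE factors, upper-quartile factors and library sizes alone; no filter and 2 stricter filters; DESeq2 1.42.0, limma-voom and limma-voom with sample weights; a non-robust fit; the replicate number as a block; removal of mitochondrial, ribosomal protein and haemoglobin genes; each library left out in turn; a test against a fold of 1.5; other thresholds; and the other list tests. An offset for transcript length and GC content was added after seeing the data.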

Results

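Messenger RNA was sequenced from granulocyte-monocyte progenitors (GMP), the bone marrow cells that give rise to neutrophils and monocytes. The cells were sorted from femurs of C57BL/6J mice aged 14 weeks. One group, called Control, came from naive mice (n = 3 animals), and the other, called Inflammation, from mice 2 days after an acute myocardial infarction (n = 3 animals). The series implies 1 comparison, which asks how transcription in these progenitors differs early after the infarction. Total counts per library were 27700816, 29430181 and 28063651 in Control and 36423876, 25411341 and 30637199 in Inflammation. The first principal component of the 1000 most variable genes, with 39.1% of the variance, put the Control libraries at -17.1, -17.7 and -21.3 and the Inflammation libraries at 10.6, 36.2 and 9.43, so Inflammation 2 stood apart from its group. Its mean correlation with its own group was 0.977, against 0.983 to 0.986 in the other libraries. The sample codes in the titles differ between the groups and none occurs in both, so a batch marked by these codes and the infarction cannot be told apart in any of the values given here. Control mice were naive, and the series has no group given a sham procedure. Effects of the procedure that produced the infarction therefore cannot be told apart from those of the infarction.

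Transcripts of eosinophil and basophil granules were lower after the infarction. Epx, the eosinophil peroxidase, had 472 ± 75.4 CPM (counts scaled to a common library total) in Control and 56.3 ± 7.98 in Inflammation (mean ± SD, n = 3 each), a log2 fold change of -3.07 ± 0.156 (SE, adjusted p = 0.000127, edgeR). Prg2, which encodes the eosinophil major basic protein, fell from 3010 ± 483 to 642 ± 114 CPM (log2 fold change -2.23, adjusted p = 0.00181), and its neighbour Prg3 fell by 2.46 on the log2 scale. The eosinophil-associated ribonucleases Ear1, Ear6 and Ear2 had log2 fold changes of -3.09, -2.85 and -2.80. Prss34, a basophil and mast cell protease, fell from 1310 ± 233 to 321 ± 68.9 CPM (log2 fold change -2.03, adjusted p = 0.00283), and Gata2, a transcription factor of stem cells and of the basophil, mast cell and eosinophil lineages, from 21.8 ± 1.70 to 8.05 ± 0.108 CPM (log2 fold change -1.44, adjusted p = 0.00283).

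Of the 19 tested members of the eosinophil, basophil and mast cell list, 10 were lower and 0 higher over all genes tested, and 14 were lower when adjusted over the list alone. The median log2 fold change of the list was -1.44. The list passed the list test with a preset correlation between genes (camera, adjusted p = 3.75e-53), and had an adjusted p = 0.154 with an estimated correlation. On GRCm38, Epx lies on chromosome 11 from 87864000 to 87875536, Prg2 on chromosome 2 from 84980461 to 84983632 and Gata2 on chromosome 6 from 88193891 to 88207032. The Ear and Prg genes and the mast cell proteases belong to families of similar sequence, and Ear1 also overlaps the pseudogene Ear-ps9, so the split of reads within these families is uncertain.

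**Figure D1:**
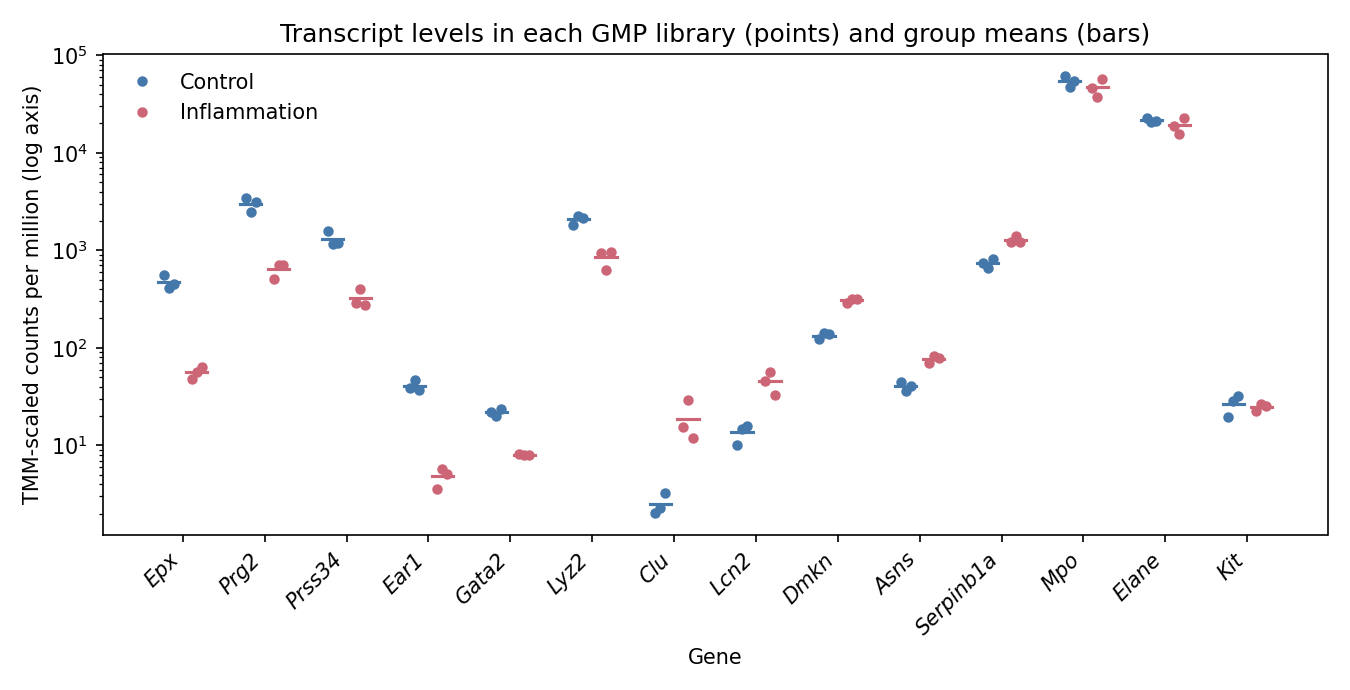
Transcript levels of 14 named genes in TMM-scaled CPM on a log axis, with 1 point per library (n = 3 per group) and a short bar for each group mean. The groups do not overlap for Epx (411 to 556 CPM in Control, 48.0 to 63.9 in Inflammation) or for the next 10 genes up to Serpinb1a, and do overlap for Mpo, Elane and Kit.

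Clu, which encodes the chaperone clusterin, rose from 2.50 ± 0.642 to 18.7 ± 9.09 CPM (log2 fold change 2.90 ± 0.352, adjusted p = 0.0145), with 29.0 CPM in Inflammation 2 and 15.3 and 11.8 CPM in the other Inflammation libraries. Lcn2, a siderophore-binding granule protein of neutrophils, rose from 13.7 ± 3.04 to 45.4 ± 11.9 CPM (log2 fold change 1.73, adjusted p = 0.0197), and Wfdc21, which encodes a small secreted protein, had a log2 fold change of 1.11. Dmkn (dermokine) rose from 134 ± 9.85 to 307 ± 15.6 CPM (log2 fold change 1.20, adjusted p = 0.00194). Asns, the asparagine synthetase, rose by 0.94 on the log2 scale (adjusted p = 0.0145), and Serpinb1a, an inhibitor of neutrophil serine proteases, from 739 ± 76.3 to 1280 ± 99.7 CPM (log2 fold change 0.79, adjusted p = 0.0241). The remaining increases named by rule were Vmn1r13 (log2 fold change 1.06), Chchd10 (0.90), Slc4a8 (0.90) and Endog (0.86). Slc4a8 lost its call with limma-voom (log2 fold change 0.89) and with an offset for transcript length and GC content (0.90). Exons of Chchd10 overlap Gm867 and Mmp11, and exons of Endog overlap Spout1. The remaining decreases were Padi2 (log2 fold change -1.47), a peptidylarginine deiminase, and Klrb1f (-1.37), a lectin-like receptor gene. Clu lies on chromosome 14 from 65968483 to 65981547 and Lcn2 on chromosome 2 from 32384633 to 32388252.

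A gene is said to pass or not to pass by the edgeR test over all genes unless another tool is named. In all, 13209 genes were tested and 62 passed at an adjusted p under 0.05, 26 higher and 36 lower in Inflammation. In each of the 62 the groups did not overlap, which was true of 3994 genes tested (30.2%, against 10% expected by chance for 3 against 3). An unadjusted p under 0.05 was reached by 2862 genes (21.7%), 1485 higher and 1377 lower. Counts of such genes within lists, given below, are to be read beside this share. With library sizes alone in place of TMM factors, 70 genes passed, 21 higher and 49 lower. The count depended on tool and library: DESeq2 gave 831 genes, 145 passed without Inflammation 2, and 16, 14, 9, 10 and 19 passed without Control 1, Control 2, Control 3, Inflammation 1 and Inflammation 3. Epx, Ear1, Ear2, Ear6, Prg2, Prg3, Prss34, Gata2 and Dmkn passed in each of these 6 fits, while the other genes named as higher or lower kept their direction and lost the call in at least 1.

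Lists of granule and lineage genes moved in different directions. The primary granule list is named for the first granules made in neutrophil development, and not all of its genes encode contents of these granules. In it 1 of 19 tested members was higher, the protease inhibitor gene Serpinb1a, and 1 lower (Lyz2, lysozyme, 2070 ± 218 CPM in Control and 849 ± 191 in Inflammation, log2 fold change -1.29, adjusted p = 0.0197). Adjusted over the list alone, 9 members were higher and 2 lower, and the list passed as higher (median 0.35, adjusted p = 0.000194 by camera, adjusted p = 0.359 with an estimated correlation). Its members Prss57 (log2 fold change 0.61, adjusted p = 0.0547) and Cst7 (0.54, adjusted p = 0.0617, and as low as 0.28 among the alternatives tried) did not pass with edgeR. DESeq2 passed 10 genes of the list, limma-voom 2 and limma-voom with sample weights 13. The most abundant granule transcripts, Mpo (54300 ± 7040 CPM in Control, 46700 ± 9690 in Inflammation) and Elane (21500 ± 946 and 19000 ± 3530), did not pass (adjusted p = 0.502 and 0.52). Of the 23 tested genes of later neutrophil granules, 2 were higher (Lcn2 and Wfdc21) and 0 lower, with 5 higher and 3 lower adjusted over the list alone. This list did not pass (camera adjusted p = 0.522), and its median of -0.12 and its test differed in sign. Wfdc21 lost its call with an offset for transcript length and GC content (log2 fold change 0.71, adjusted p = 0.0798).

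The monocyte and macrophage list passed as lower (23 tested, median -0.27, camera adjusted p = 0.00778, adjusted p = 0.525 with an estimated correlation). In it 1 gene was lower, Lgals3, which encodes galectin-3 (log2 fold change -0.92, adjusted p = 0.044, not past the test with limma-voom or a non-robust fit), and 3 were lower and 1 higher adjusted over the list alone. Adgre1 (log2 fold change -0.96), Cx3cr1 (-0.85) and Fn1 (-0.51) did not pass with edgeR. DESeq2 passed 3 genes of this list, limma-voom 0 and limma-voom with sample weights 7. The call of this list ended with fry (adjusted p = 0.185) and without Control 2 (median -0.21, adjusted p = 0.052), and without Inflammation 2 the median was -0.16. In the list of myeloid transcription factors (27 tested, median -0.18, camera adjusted p = 0.00253, adjusted p = 0.359 with an estimated correlation), Gata2 was lower, 21 members had a negative log2 fold change, and 4 were lower adjusted over the list alone. Irf8, a factor of monocyte and dendritic cell development, had 1040 ± 102 CPM in Control and 627 ± 193 in Inflammation (log2 fold change -0.74, adjusted p = 0.119), with 407 CPM in Inflammation 2. Rara (log2 fold change -1.19), Irf5 (-0.72), Cebpa (-0.78) and Cebpb (-0.34) did not pass with edgeR either, nor did Spi1 (-0.11), Cebpe (-0.64, and between -0.94 without Inflammation 3 and -0.33 without Inflammation 2) and Gfi1 (0.09). With single libraries left out, Spi1 ran from -0.18 (Inflammation 1) to -0.025 (Inflammation 2) and Gfi1 from 0.0063 (Inflammation 3) to 0.15 (Control 3). In this list edgeR and limma-voom passed 1 gene each, DESeq2 4 and limma-voom with sample weights 7.

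Further lists passed as lower with no member past the gene test in edgeR. The erythroid list had a median of -0.59 over 20 tested genes (camera adjusted p = 0.0182, adjusted p = 0.548 with an estimated correlation), with Gfi1b at -1.10, Klf1 at -0.89, Gata1 at -0.76 (past the test without Inflammation 2) and Tspan33 at -0.58. Adjusted over the list alone, 5 erythroid genes were lower and 1 higher, and 8 had an unadjusted p under 0.05. The erythroid call ended without Inflammation 2 (median -0.35, adjusted p = 0.0915), Control 1 (-0.54, adjusted p = 0.172) or Inflammation 3 (-0.50, adjusted p = 0.13), and without haemoglobin, mitochondrial and ribosomal protein genes (-0.38, adjusted p = 0.236). It also ended with fry (adjusted p = 0.195), with a minimum mean count of 100 (adjusted p = 0.0511) and with limma-voom and sample weights (median -0.38, adjusted p = 0.121). The list of Cdk inhibitors and quiescence genes had a median of -0.21 over 17 genes (camera adjusted p = 0.0182, adjusted p = 0.359 with an estimated correlation), with Klf6 and Btg1 each at -0.56, Cdkn2c at -0.47 and Foxo1 at -0.71. Adjusted over the list alone, 2 of its genes were lower, and 9 had an unadjusted p under 0.05. Its call ended with fry (adjusted p = 0.0807), without Control 2 (median -0.23, adjusted p = 0.0751) or Inflammation 3 (-0.27, adjusted p = 0.0718), with the length and GC offset (-0.23, adjusted p = 0.0574) and without genes shared with other lists (-0.17, adjusted p = 0.109). Its median was -0.35 without Control 1 and -0.33 without Inflammation 2. The immediate early list had a median of -0.24 over 23 genes (camera adjusted p = 0.0185, adjusted p = 0.488 with an estimated correlation), with Dusp6 at -0.86, Btg2 at -0.47 and Hspa1b at -1.93. The Hspa1b value rested on Control 2 (15.3 CPM, against 6.11 and 2.11 in the other Control libraries) and was -0.99 without it. Adjusted over the list alone, 1 of its genes was lower, and 8 had an unadjusted p under 0.05. Its call ended with fry (adjusted p = 0.146), without Control 2 (median -0.18, adjusted p = 0.137), with the length and GC offset (-0.13, adjusted p = 0.131) and with limma-voom and sample weights (adjusted p = 0.105). DESeq2 passed 3, 2 and 2 genes of these lists, limma-voom 0, and limma-voom with sample weights 3, 7 and 6.

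Genes of ribosomes and nuclear genes of mitochondrial respiration were higher as lists with the preset correlation, by small amounts. The list of cytosolic ribosomal proteins had been fixed beforehand as a technical check. Of 87 tested cytosolic ribosomal protein genes, 86 had a positive log2 fold change, with a median of 0.38. Over all genes tested 1 was higher, Rps21, from 73.3 ± 6.40 to 117 ± 4.83 CPM (log2 fold change 0.68, adjusted p = 0.0224), and 68 were higher adjusted over the list alone. DESeq2 passed 44 of these genes, limma-voom 1 and limma-voom with sample weights 62. The list passed (camera adjusted p = 2.11e-29), with an adjusted p = 0.359 with an estimated correlation. Rps10 (log2 fold change 0.62), Rpl27 (0.57) and Rpl30 (0.55) lay just outside the threshold, with adjusted p = 0.0502, 0.0513 and 0.054, and Rps10 and Rpl27 passed without Inflammation 2. With the length and GC offset the list median was 0.20 (adjusted p = 6.58e-09), and Rps21 was at 0.33 and did not pass (adjusted p = 0.13). Ribosomal protein genes took 2.33%, 2.56% and 2.30% of counts in Control and 2.79%, 3.25% and 2.82% in Inflammation, the highest share being that of Inflammation 2. Processed pseudogenes, many of them copies of such genes, took 3.21%, 3.31% and 3.17% in Control and 3.61%, 3.85% and 3.70% in Inflammation, and reads cannot always be assigned between a gene and its copies.

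Of 58 tested oxidative phosphorylation genes, 57 had a positive log2 fold change, with a median of 0.28 (camera adjusted p = 2.99e-14, adjusted p = 0.359 with an estimated correlation). None passed over all genes with edgeR, 29 were higher adjusted over the list alone, and 37 had an unadjusted p under 0.05. DESeq2 passed 13, limma-voom 0 and limma-voom with sample weights 44. With the length and GC offset the median was 0.16 (adjusted p = 0.00129). Uqcrh of complex III had a log2 fold change of 0.46, Atp5g3 of the ATP synthase 0.65, and Ndufb9 and Ndufs6 of complex I 0.39 and 0.36. With the offset these genes were at 0.11, 0.35, 0.15 and 0.035. The oxidative phosphorylation list holds no gene of the mitochondrial genome. Of 13 such genes, tested as another list, 12 had a negative log2 fold change (median -0.17). That list did not pass (camera adjusted p = 0.362). The 22 tested genes of the TCA cycle had a median of 0.20 (camera adjusted p = 0.00813, adjusted p = 0.359 with an estimated correlation). Of these, 0 passed with edgeR over all genes or adjusted over the list alone, 6 had an unadjusted p under 0.05, DESeq2 passed 2, limma-voom 0 and limma-voom with sample weights 3. The call ended without Control 2 (median 0.16, adjusted p = 0.0591) or Inflammation 3 (0.20, adjusted p = 0.0525). Among its genes Suclg1 had a log2 fold change of 0.40, Sdhd 0.31 (0.11 with the offset), Pdha1 0.30 and Fh1 0.40 (0.25 without Inflammation 2). The 35 genes of ribosome biogenesis had a median of 0.23 (camera adjusted p = 2.44e-06, adjusted p = 0.359 with an estimated correlation). Of these, 0 passed with edgeR over all genes, 3 were higher adjusted over the list alone, 15 had an unadjusted p under 0.05, DESeq2 passed 5, limma-voom 0 and limma-voom with sample weights 17. The nucleolar protein genes Npm1 (log2 fold change 0.71) and Ncl (0.76) were in this list, as were Pa2g4 (0.74, and 0.49 but past the test without Inflammation 2) and Gnl3 (0.36). Ncl had 1350 CPM in Inflammation 2 and 741 and 753 CPM in the other Inflammation libraries, and its log2 fold change was 0.42 without that library. Lists of other genes, matched to the ribosomal protein and oxidative phosphorylation genes on transcript length, GC content and expression, had a median of 0.16, and 0.14 where only protein-coding genes were drawn, against 0.33 for these genes together.

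The list of amino acid synthesis and stress genes controlled by ATF4 passed as higher (25 tested, median 0.23, camera adjusted p = 0.00154, adjusted p = 0.342 with an estimated correlation). Asns was its 1 member past the gene test, and 3 were higher adjusted over the list alone. Without Inflammation 2 the median was 0.15, and with the length and GC offset 0.35. The serine synthesis genes Psph (log2 fold change 0.52) and Phgdh (0.39) and the mitochondrial enzyme Shmt2 (0.26) did not pass over all genes with edgeR. DESeq2 passed 3 genes of this list, limma-voom 1 and limma-voom with sample weights 5. The redox list passed as higher (31 tested, median 0.14, camera adjusted p = 0.00447, adjusted p = 0.342 with an estimated correlation). In it Gclm, a subunit of the enzyme that starts glutathione synthesis, rose from 76.5 ± 6.34 to 128 ± 13.1 CPM (adjusted p = 0.0241), and 2 genes were higher adjusted over the list alone. Exons of Gclm overlap Gm6061. The redox median was 0.067 without Control 1 and 0.083 with library sizes alone. Prdx3 (log2 fold change 0.47), Prdx6 (0.33) and Sod2 (0.35) did not pass with edgeR. DESeq2 passed 3 redox genes, limma-voom 1 and limma-voom with sample weights 8.

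**Figure D2:**
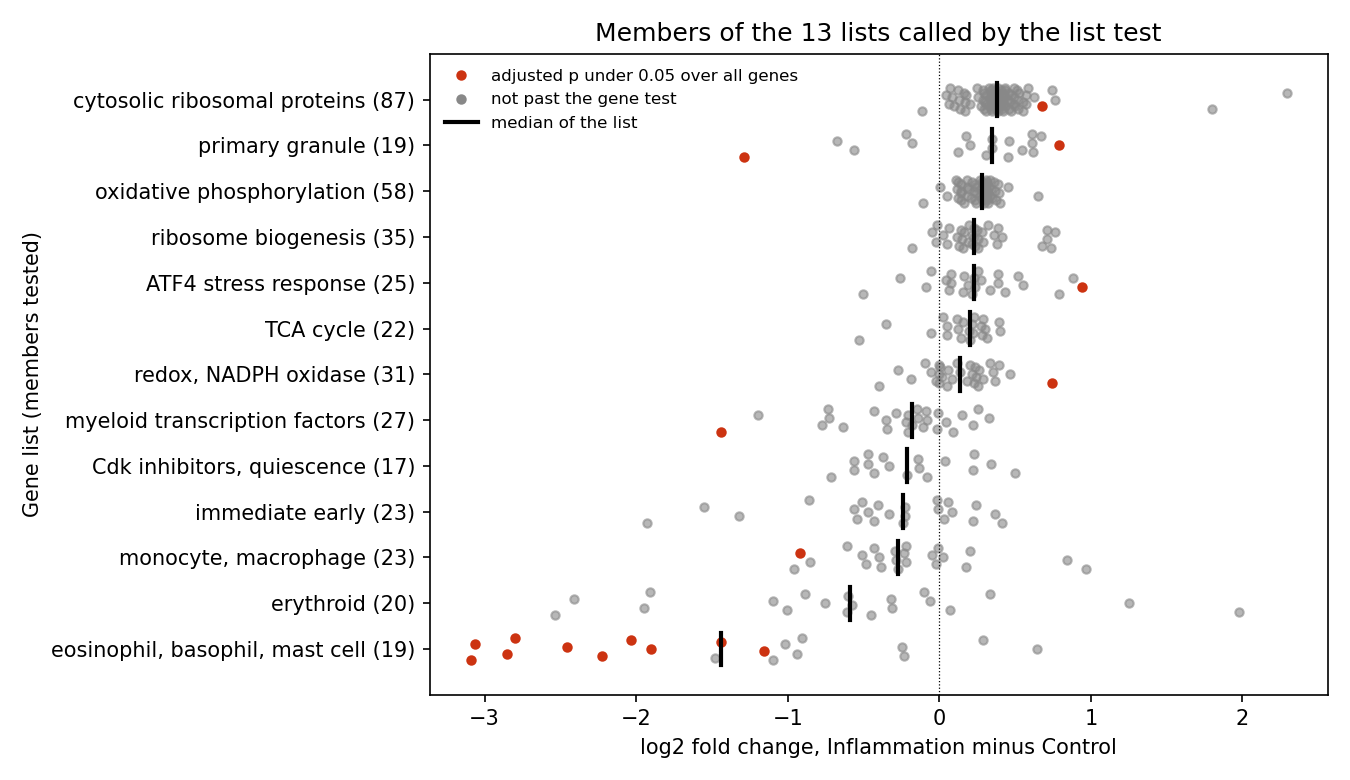
Log2 fold changes, Inflammation minus Control, of every tested member of the 13 lists that passed the list test with a preset correlation, with 1 point per gene, the number of members in parentheses and a vertical bar at each list's median. Members past the gene test over all genes are red; the list medians run from -1.44 for the eosinophil, basophil and mast cell list to 0.38 for cytosolic ribosomal proteins.

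In all, 13 of the 37 lists tested passed with the preset correlation, 7 higher and 6 lower. With a correlation estimated for each list 0 passed and 4 had an unadjusted p under 0.05, while fry, which asks only whether a list's genes move on balance in one direction, passed 10. Of these, 9 were among the 13, and the other was the lymphoid list (higher, fry adjusted p = 0.0146). Other splits of the same 6 libraries into 3 and 3 passed between 5 and 17 lists with the preset correlation. Those splits mix libraries of both groups and keep part of any group difference, so these counts are not a clean rate of false calls.

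Gene lists of lipid use did not pass. For fatty acid oxidation, 25 genes were tested and the median was 0.08 (camera adjusted p = 0.425). For fatty acid uptake and lipolysis the median was 0.05 over 24 genes (0.51), for fatty acid synthesis 0.02 over 15 genes (0.585) and for cholesterol synthesis -0.10 over 25 genes (0.679). None of these genes passed with edgeR or limma-voom. An unadjusted p under 0.05 was reached by 2, 6, 2 and 2 genes of the respective lists, and DESeq2 passed 1, 1, 0 and 0 and limma-voom with sample weights 2, 2, 0 and 0. Adjusted over the list alone, 1 gene of uptake and lipolysis was higher and 0 of the other lists. Cpt1a, which controls fatty acid entry into mitochondria, had 17.4 ± 2.57 CPM in Control and 19.0 ± 4.43 in Inflammation (log2 fold change 0.13, adjusted p = 0.708). Ldlr, the LDL receptor gene, had a log2 fold change of -0.75 (adjusted p = 0.208), which was -0.31 without Control 2, Fasn 0.28 and Hmgcs1 -0.05. Cd36, a fatty acid transporter gene, had between 1 and 3 counts per library, too few to test.

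Cell division genes did not pass either. The median was -0.01 over 30 genes of DNA replication (camera adjusted p = 0.986, with a test direction that was positive) and -0.06 over 30 genes of mitosis (0.228, and 0.0343 without a count filter; the median ran to -0.11 without Control 2), and Mki67, the gene of the proliferation marker Ki-67, had a log2 fold change of -0.14 (adjusted p = 0.492). The Mki67 value was -0.25 without Inflammation 2 and -0.096 without Inflammation 3. Myc had a log2 fold change of -0.18 (adjusted p = 0.558). The glycolysis list had a median of 0.06 (adjusted p = 0.0611), with 4 of 23 genes higher adjusted over the list alone. Interferon-stimulated genes had a median of -0.13 over 31 genes (adjusted p = 0.421), while the median was 0.084 without Inflammation 2 and -0.23, past the test (adjusted p = 0.0407), without Inflammation 3. The lists of NF-kB targets (median -0.05), cytokine receptors and STAT3 targets (-0.07), adhesion and homing (-0.02), unfolded protein response (0.16), glucocorticoid response (-0.22), hypoxia (0.16), TGF-beta, BMP and Notch (-0.10), apoptosis and p53 (0.0038), replication histones (0.10) and mitochondrially encoded genes (-0.17) did not pass. For other cell types the lists that did not pass were dendritic cells (-0.02), stem and multipotent progenitors (-0.04), megakaryocytes (0.03), lymphoid cells (0.10, past fry only) and stroma, adipocytes and endothelium (-0.10, 8 of 26 genes tested). Median and test differed in sign for the glucocorticoid, apoptosis and megakaryocyte lists as well. Adjusted over the list alone, genes were higher and lower in number by 4 and 1 for glucocorticoid response, 2 and 4 for dendritic cells, 3 and 2 for stem cells, 2 and 3 for adhesion, 1 and 1 for cytokine receptors and for stroma, 4 and 0 for hypoxia and 3 and 0 for lymphoid cells, and 0 and 0 for the other lists just named. The glucocorticoid list held 2 higher genes, Lcn2 and Mt1, and the stem cell list 1 lower gene, Gata2. The sex-linked list had 1 gene above the count filter, Kdm5d (log2 fold change -0.07), and could not be tested as a list. In the other 22 lists without a call, none of 487 list entries passed with edgeR or limma-voom, 92 had an unadjusted p under 0.05, DESeq2 passed 28 and limma-voom with sample weights 76. Over all genes tested, 21.7% had an unadjusted p under 0.05.

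None of the markers of the sort passed with edgeR. The labels give the gate as lineage-negative cells positive for Sca1, Kit, CD34 and CD16/32. GMP are usually defined as Sca1-negative, and the counts do not settle whether the sorted cells were positive or negative for Sca1. Kit had 26.8 ± 6.44 CPM in Control and 24.8 ± 2.34 in Inflammation (adjusted p = 0.741), and Fcgr3, which encodes CD16, 1030 ± 130 and 1000 ± 111 CPM (adjusted p = 0.885). Cd34 had 190 ± 3.83 and 120 ± 18.9 CPM (log2 fold change -0.66, adjusted p = 0.054, past the test without Inflammation 2), and Ly6e -0.46 (adjusted p = 0.0921). Ly6a, the gene of Sca1, had 8.05 ± 2.87 CPM in Control and 7.82 ± 1.01 in Inflammation (adjusted p = 0.94). Of 10 tested sort genes 0 passed with edgeR or limma-voom, while 2 had an unadjusted p under 0.05 and 2 passed with DESeq2 and with limma-voom with sample weights (Cd34 and Ly6e). Ly6e was in this fixed set although the gate as labelled does not name its protein. Fcgr2b (log2 fold change -0.15), Ptprc (0.14), Itgam (-0.17), Ly6g (-0.12) and Cd8a (0.19) did not pass. Cd4, Klrb1c, Itgax and Il7r, whose proteins were depleted before the sort, stayed below the count filter, and Cd19 had 0 counts in each of the 6 libraries, where a count of 0 allows up to 3. Of the remaining genes fixed for naming, Csf3r had a log2 fold change of -0.16, Il1r1 -0.04, S100a8 0.04, S100a9 -0.31, Hbb-bs -1.95 and Cxcr4 -0.40, and none of them passed with edgeR. Single libraries left out moved Csf3r to -0.35 (Inflammation 3) or -0.060 (Control 3), S100a9 to -0.49 (Inflammation 3) or -0.14 (Control 3) and Cxcr4 to -0.61 (Control 1) or -0.24 (Control 2).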

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

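All choices below were set before the data were examined, except the offset for transcript length and GC content. All 62 genes kept their direction under every alternative in which they were tested. Where a count moved, the cause was not tested except where fewer samples or a changed threshold made the difference. The 62 genes (26 higher, 36 lower) became 302 (136 and 166) without a count filter, 831 (473 and 358) with DESeq2, 2294 (1274 and 1020) with limma-voom and sample weights, 101 (41 and 60) with the length and GC offset, 13 (2 and 11) against a fold of 1.5, 12 (1 and 11) at an adjusted p under 0.01 and 534 (305 and 229) at one under 0.1. RLE factors (73), upper-quartile factors (66), library sizes alone (70), stricter filters (81 and 58), limma-voom (57), the non-robust fit (58) and removal of mitochondrial, ribosomal protein and haemoglobin genes (61) stayed within 1.5 times. With single libraries left out the count ran from 9 without Control 3 to 145 without Inflammation 2 (higher 1 to 59, lower 8 to 86), and was 16 without Control 1, 14 without Control 2, 10 without Inflammation 1 and 19 without Inflammation 3. Clu, Lcn2, Asns, Lyz2, Serpinb1a, Gclm, Rps21 and Lgals3 kept their direction in each of these fits and lost the call in 4 or 5 of 6; Epx, Ear1, Ear2, Ear6, Prg2, Prg3, Prss34, Gata2 and Dmkn passed in each.

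The replicate numbers shared by the groups belong to different animals. Deviations of same-numbered libraries from their group means correlated at 0.0547, 0.135 and 0.105, under the bound of 0.1 in 1 pair, so the numbers were not taken to pair the samples, although each library correlated best with its own number, a hint from the data only. With the replicate block 172 genes passed (89 higher, 83 lower), among them 61 of the 62, Prg3 being the exception (adjusted p = 0.0608), and 794 (438 and 356) with DESeq2 and the block.

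The 13 lists became 0 (0 higher, 0 lower) with an estimated correlation, and lists passing as lower became 2 with fry. With single libraries left out, 9 to 15 lists passed (6 to 9 higher, 3 to 6 lower, the fewest without Control 2). The eosinophil, basophil and mast cell median ran from -1.50 to -1.20 in those fits. Sort genes past the test rose from 0 to 1 with library sizes alone, with a CPM filter and with the replicate block, and to 2 with no filter, DESeq2, limma-voom with sample weights and DESeq2 with the block, and ran from 0 to 1 with single libraries left out; the genes were Cd34 and, where 2 passed, Ly6e.

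Direction here is the sign of the log2 fold change of a gene and of the test of a list. Results that reversed passed neither in the reported fit nor in the fit that reversed them. With limma-voom and sample weights Fcgr3 was 0.057, Cpt1a -0.033, Fasn -0.088 and Cd8a -0.11. Ly6a was 0.0075 with limma-voom, 0.0098 with the replicate block and 0.011 with DESeq2 and the block. S100a8 was -0.0037 with library sizes alone. The length and GC offset gave S100a8 -0.39, Spi1 0.063, Csf3r 0.024 and the cholesterol list -0.0070, where the test turned and the median kept its sign. Left-out libraries gave ranges of -0.32 to 0.033 for Kit, -0.14 to 0.044 for Fcgr3, -0.29 to 0.26 for Ly6a, -0.24 to 0.14 for Il1r1, -0.32 to 0.012 for Myc, -0.066 to 0.27 for Cpt1a, -0.18 to 0.14 for Hmgcs1, -0.035 to 0.48 for Fasn, -0.14 to 0.16 for S100a8, -0.13 to 0.81 for Cd8a, -0.39 to 0.085 for Itgam, -0.46 to 0.19 for Ly6g, -0.00035 to 0.12 for fatty acid oxidation, 0.0062 to 0.27 for fatty acid synthesis (only the test turned, without Control 1), -0.019 to 0.13 for fatty acid uptake and lipolysis (only the median turned, without Inflammation 1), -0.21 to 0.054 for cholesterol synthesis and -0.23 to 0.084 for interferon-stimulated genes, whose lowest value, without Inflammation 3, passed. Depth limits the genes of low level, and for Cd8a (0.425 CPM in Control) and Il1r1 (0.958 CPM) no difference was detectable.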

Other observations

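The tests of paralog families, of matched coding genes, of eosinophil against basophil members, of pseudogenes, of list splits and of families by symbol, the length and GC offset and the genes named in the next paragraph were chosen after the results were seen; the others were set before.

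The 62 genes also held genes outside the naming rule. Alox15, a lipoxygenase of eosinophils, had a log2 fold change of -2.43 (adjusted p = 0.0215, edgeR), Cd200r3, a receptor of basophils and mast cells, of -1.90 (adjusted p = 0.0224) and Mcpt8, a basophil protease, of -1.16 (adjusted p = 0.0197). Csf1, the gene of a macrophage growth factor, was at -1.29 (adjusted p = 0.0271), Apoe, a lipid carrier, at -1.27 (adjusted p = 0.0211) and Tgfbi, an extracellular matrix protein, at -1.13 (adjusted p = 0.0236). Ccl9, a chemokine of myeloid cells, rose from 145 ± 4.87 to 243 ± 23.5 CPM (adjusted p = 0.0197), and Mt1, a metallothionein, had a log2 fold change of 0.76 (adjusted p = 0.0271). Each gene of this paragraph kept its direction but lost its call without Control 3, where 9 genes passed.

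Of 121 gene groups formed from shared symbol stems with at least 10 tested members, 14 passed, 9 as higher and 5 as lower. Among the higher were the mitochondrial ribosomal protein genes (81 tested, 79 positive, median 0.27, camera adjusted p = 7.42e-14), the Psm genes, mostly of proteasome subunits (50 tested, 47 positive, median 0.26, adjusted p = 1.18e-09) and the genes with the stem Eif, mostly translation initiation factors (58 tested, 50 positive, median 0.26, adjusted p = 6.71e-07, with 1 gene, Eif3i, past the gene test). The others were Nduf, Cox, Eef, Hmgb (14 tested, median 0.73, the largest of the 14 in size), Timm and Polr. Symbols of pseudogene copies were not left out of these groups. A group such as Hmgb can therefore hold copies, and its median cannot be read as that of its coding genes. The lower groups were Arhgef, Map, Zbtb, the Zfp zinc finger genes (332 tested, 59 positive, median -0.25, adjusted p = 3.93e-06) and the genes with the stem Irf, which are interferon regulatory factors and their binding proteins (10 tested, 1 positive, median -0.42, adjusted p = 0.00876). None passed with an estimated correlation, where adjusted p = 0.646 was the lowest. Of 1158 tested processed pseudogenes, 81.7% had a positive log2 fold change, with a median of 0.40, against 46.3% of all other genes, with a median of -0.03, and 2 passed, Gm12033 and Gm13394, the latter with 0 counts in each Control library and a mean of 4.97 CPM in Inflammation. Among the 2632 genes with the shortest transcripts (53 to 1487 nucleotides) the median was 0.21, and 0.12 over the 1437 protein-coding genes among them.

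The eosinophil, basophil and mast cell list passed as lower with the preset correlation, with adjusted p = 0.154 with an estimated correlation. Without Inflammation 2 its median was -1.501, which argues against that library as the cause, and without the Ear, Prg and protease families the median of the 12 remaining members was -0.976, which argues against reads shared between paralogs as the whole cause. The median of the 8 eosinophil members (-2.63) minus that of the 10 basophil or mast cell members (-0.98) was -1.653 (exact two-sided permutation p = 0.00501 over members, which are not independent). Genes that other progenitors also transcribe would fall less, so a single loss of cells that carry all these transcripts cannot be told apart from separate losses. Lower transcription within the cells was not tested either, so a loss of cells is not shown. A batch stays open, since 0 sample codes occur in both groups. A biological difference 2 days after the infarction also stays open. It was not tested separately from a batch, or from effects of the procedure that produced the infarction, since Control mice were naive.

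Ribosomal protein and respiratory chain lists passed as higher with the preset correlation, with adjusted p = 0.359 for each with an estimated correlation. Lists matched on length, GC content and expression had a median of 0.161 (0.145 among protein-coding genes alone), against 0.332 observed, a difference of 0.1709, and an offset for length and GC left 0.187, which argues against these properties as the whole cause while part of the size is shared with matched genes. Without Inflammation 2 the ribosomal protein median was 0.3236, and the genes called lower held 0.8586% of Control counts, so neither that library nor a loss of those counts accounts for the lists. Genes that fell without passing were not part of this share, so a wider loss of counts was not tested. Processed pseudogenes lay 0.2997 above matched genes (and 0.12 above the genes they were copied from, over 165 named copies). A difference between the groups in reads or library preparation would give this, so a technical difference that follows the groups may contribute. Reads of raised genes counted at their copies would lift pseudogenes too. With an equal miscounted share in both groups, they would lift a copy by no more than its gene rose. Of the 165 copies 69.7% lay above their gene, which argues against such reads as the whole cause for these copies. As part of the cause they were not separated from a technical difference. A biological rise in expression of ribosomal and nuclear-encoded mitochondrial genes also stays open and was not separated from a technical difference.

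Inflammation 2 stood apart on the first principal component. After thinning all libraries to an equal total over the tested genes its gap to the nearest Inflammation library was 23.92, against 25.6 before, which argues against depth. Across 8147 genes, which are not independent replicates, its difference from 1 Inflammation library correlated with the shift of the other from Control at 0.1928 and 0.232, on either side of the bound of 0.2 set beforehand, so a larger shift of the same genes cannot be told apart from some other difference of this animal or library.

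With 3 against 3 the splits are too few for a share under 0.05: 1 of the 10 splits, the real one, gave as many as 62 genes, the highest of the others 1. Each other split sets 2 libraries of one group with 1 of the other. It therefore keeps part of any group difference and adds the rest to the spread within its sides. Few gene calls there were likely beforehand, so these counts decide nothing, and the list calls there are not a clean rate of false calls. For the lists, 2 of the 10 splits, the real one included, gave at least 13, the highest of the others 17. That split set Control 1, Inflammation 2 and Inflammation 3 against the rest and gave 0 lists with fry. The median of the eosinophil, basophil and mast cell list was -1.44 in the real split and at most 0.67 in size in the others. For ribosomal proteins these values were 0.38 and 0.24, for the monocyte list -0.2706 and 0.2709, and for the immediate early list -0.239 and 0.256. For every other called list no other split had a median as large. These lists were picked by their call in the real split, and the other splits keep only part of any group difference. Smaller medians there were therefore likely beforehand and decide nothing. With the preset correlation, camera passed the eosinophil, basophil and mast cell list in 6 of the 9 other splits. It passed ribosomal proteins in 7 and oxidative phosphorylation in 5.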
